A study of Mus musculus with 4 samples.

How the data were processed

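Gene expression was measured by droplet single-cell RNA sequencing in 4 libraries from C57BL/6J mice, an inbred laboratory strain. Per the labels, cell suspensions from the small intestinal epithelium and from whole lung were obtained by mechanical and enzymatic dissociation, and each tissue gave 1 library of single cells (singlets) and 1 library of clusters of several attached cells (multiplets). The labels name no separate animals and do not say how singlets and multiplets were separated. Libraries were made with the Chromium Single Cell 3' v3 kit, which counts unique molecular identifiers (UMIs) near the 3' end of transcripts. Cell Ranger 4.0.0 and the mouse build mm10 are named in the submitters' processing notes.

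For each library the authors deposited a table of raw UMI counts per gene symbol and barcode and an annotation table per barcode. The deposited values were whole numbers with a different total per barcode, so they were treated as counts that had not been normalized. The annotation tables hold the authors' quality flag and, for singlets, their cell class. How classes and the flag were made is not given in the sources used here. All barcodes in the count tables carried the authors' passing flag. In the small intestine, counts covered 5279 singlet barcodes of 6710 listed and 3671 multiplet barcodes of 5607 listed as passing. In the lung they covered 6084 of 8410 and 4729 of 8630. The remaining 1936 and 3901 listed multiplet barcodes were not analysed here. The tables share 14982 gene symbols in the small intestine and 19042 in the lung, and genes outside these sets were left out of ratios.

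No further filter was set on barcodes. Library totals were 47764845 UMIs for intestinal singlets, 50645279 for intestinal multiplets, 56639425 for lung singlets and 66277622 for lung multiplets. With 1 library per group there was no replicate, no test was run and no p-value was computed. Shares carry exact Clopper-Pearson intervals and sums carry exact Poisson intervals at 95%, which cover counting error only and not differences between animals, dissociations or libraries. For a share of 0, the limit that 3 counts give is printed as well. A difference is called higher or lower by size alone, at more than 1.5-fold.

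UMIs were summed over the barcodes of each library and divided by the library total to give CPM, UMIs scaled to the same total in every library. The ratio of multiplet to singlet CPM was taken per gene on the raw sums without a pseudocount, for genes with at least 50 UMIs in either library. Marker lists for the cell types of each tissue, and gene lists for functions such as antimicrobial defence, lipid absorption, surfactant, matrix, antigen presentation and the dissociation response, were fixed before the data were examined, as were the size limits, the rule for named genes and most of the alternatives. For each list the number of members past the limit, the ratio of the summed CPM and the percentile of the list's median among 10000 random lists matched on mean expression were computed. Named genes are the 12 with the highest and the 12 with the lowest ratio in each tissue among genes with at least 20 CPM in the higher library, leaving out Gm-numbered, Rik and mitochondrial genes and antigen receptor segments. Members of the fixed lists may be named as well.

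Marker co-detection needed no classes. Each barcode was thinned at random to 1000 UMIs, and a barcode was counted when each of 2 marker lists had at least 2 UMIs. No barcode was shallower than 1000 UMIs.

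Multiplets were decomposed with the authors' singlet classes as reference. Class profiles were sums of UMIs over the class. The genes used were the union over classes of the 40 with the highest ratio to the next class (with 10 CPM added), which gave 400 genes in the small intestine and 520 in the lung. Each barcode was fitted as a Poisson mixture of the profiles by expectation maximization with 300 iterations, and a class was called at a weight of 0.15 or more. Background was measured in the same way in the singlets, each fitted with profiles from the other randomly drawn part of the singlets. For sensitivity, 50 synthetic doublets per pair of classes were made by adding 2 such singlets. Each barcode with at least 2 classes added 1 to every pair of its classes. Expected counts came from a symmetric table with an empty diagonal and the same total per class. Pairs with an expected count of at least 5 are reported, and the 8 highest and 4 lowest in each tissue are named together with pairs fixed beforehand. For genes outside the mixture, the UMIs summed over multiplets were divided by the sum predicted by the fitted weights and the full profiles, for genes with at least 200 UMIs observed or predicted. The 10 highest and 5 lowest of these are named.

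Scrublet in scanpy 1.11.5 marked 85 of 5279 intestinal singlets (1.61%) and 126 of 6084 lung singlets (2.07%) as doublets. They were kept, and the fit was repeated with a reference that left them out. Alternatives covered the scaling (edgeR 4.0.16 TMM, DESeq2 1.42.0 size factors, CPM without mitochondrial, ribosomal protein and haemoglobin genes, and the mean of each barcode's CPM), the count minimum, the thinning depth, the weight limit, non-negative least squares in place of the Poisson mixture, the number of genes per class and the expectation for pairs. Chosen after seeing the data were merged classes, thinning to 5000 UMIs before the fit, and singlets limited to those at least as deep as the shallowest multiplet. Gene positions are those of GENCODE M21 on GRCm38, the same assembly as mm10, and count from 1.

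The summed comparison, the mixture fit with 1 pair per tissue and the genes outside the mixture were tested on simulated counts with the real genes, class profiles and library sizes. For the summed comparison, 50 genes were simulated at each of the folds 0.25, 0.5, 2 and 4. In the small intestine (11686 genes) the limit recovered 100%, 98%, 98% and 100% of them, and 0.174% of unchanged genes passed it. In the lung (14713 genes) it recovered 100% at each fold, and 0.317% of unchanged genes passed. In 2000 simulated mixed barcodes both classes were called in 97.8% for the small intestine and in 100% for the lung. Of 2000 simulated 1-class barcodes 2.95% and 0.05% were given more than 1 class. These barcodes were drawn from the same profiles that the fit used, without variation between cells of a class, so high recovery was built in. They do not give error rates for real cells: 43.5% of held-out intestinal and 11.3% of lung singlets were given at least 2 classes. In synthetic doublets of real Paneth and stem singlets both classes were called in 46%. A Paneth with stem ratio of 3.20 in the simulated intestinal barcodes came back as 3.30, and an endothelial with type II pneumocyte ratio of 2.49 in the simulated lung barcodes came back as 2.50. All 200 simulated genes doubled outside the mixture were found in both tissues. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.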

Results

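The data were UMI counts per gene in 4 libraries, 1 each of singlets and multiplets from mouse small intestinal epithelium and from mouse whole lung. Multiplets are clusters of cells that share a droplet, so 1 barcode can hold RNA of several cells. Each group had 1 library and the labels name no separate animals, so no difference between libraries could be set against a spread between replicates. Intestinal singlets had a median of 8759 UMIs and 2725 genes per barcode (1694 to 49697 UMIs), and intestinal multiplets had 12603 UMIs and 3271 genes (1591 to 50940 UMIs). Lung singlets had a median of 7896 UMIs and 2830 genes (2175 to 57498 UMIs), and lung multiplets had 11934 UMIs and 3379 genes (5006 to 145206 UMIs). Multiplets had 1.44 times the median UMIs of singlets in the small intestine and 1.51 times in the lung. Median mitochondrial shares were 4.34% and 4.72% of UMIs in intestinal singlets and multiplets and 3.43% and 3.31% in those of the lung.

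Singlets give the cell classes that the multiplets can be built from. Early progenitors were 22% of the 5279 intestinal singlets (20.9 to 23.2), transit amplifying cells 19.9%, goblet cells 18.7% and late progenitors of the type called late-1 13.8%. Stem cells, which renew the epithelium from the crypt base, were 11.1% (10.3 to 12). Late-2 progenitors were 3.85%, enterocytes 3.62%, enteroendocrine cells 3.32%, tuft cells 2.12% and Paneth cells, the secretory cells that lie between stem cells at the crypt base, 1.67% (1.34 to 2.05). In the lung the class called fibroblast-1 was 48.7% of 6084 singlets (47.5 to 50) and type II pneumocytes, which make surfactant, were 16.6%. Fibroblast-2 cells were 8.68%, T cells 5.49%, macrophages 4.65%, alveolar macrophages 3.73%, B cells 3.12%, ciliated cells 2.98%, natural killer (NK) cells 2.83%, endothelial cells 1.96% and club cells 1.0%. The reference was thin for mesothelial cells, with 10 singlets, and for type I pneumocytes, the flat cells of gas exchange, with 6.

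The comparison of summed expression in the small intestine asks which RNA was more or less abundant in multiplets than in singlets. Antimicrobial genes of Paneth cells stood highest in multiplets. Defa22, a defensin, reached 6.10 times its singlet level (6.04 to 6.16; 999.5 CPM in singlets and 6095 in multiplets), and Ang4, an antimicrobial ribonuclease, reached 4.0 times (3.92 to 4.09). Lyz1, the Paneth cell lysozyme, was 2.47 times higher (2.46 to 2.48) at 9522 CPM in multiplets. Tuft cell genes were lower, with Rgs13 at 0.315 times and the tuft cell kinase Dclk1 at 0.445 times the singlet level. Stem cell genes were lower as well, with Ascl2, a transcription factor of stem cells, at 0.506 times (0.473 to 0.541) and Lgr5, a receptor that marks them, at 0.554 times (0.509 to 0.603).

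Of the 11 antimicrobial genes 9 were over 1.5-fold higher and none lower, and the list's summed CPM was 2.06 times that of singlets. The Paneth markers gave 7 of 8 higher and a summed ratio of 2.10, but their sizes differed: Defa24 stood at 1.96 times and Defa30 at 1.41 times. Among the 12 highest genes were also Defa21 (5.92 times), Defa35 (4.49), Defa34 (3.88), Defa36 (3.54), Mptx2 (3.10) and Defa29 (2.85). These defensins have near-identical sequences, so the split of their UMIs among them is uncertain. In singlets 68.3% of Defa22 UMIs lay in 10 barcodes, against 12.5% in multiplets, and with each barcode weighted equally the ratio was 9.24 for Defa22, 9.34 for Defa21, 6.89 for Defa35, 5.93 for Defa34, 6.01 for Defa36, 5.48 for Mptx2 and 4.50 for Defa29. The other 3 of the 12 highest were Tmigd1 (2.82 times), Nupr1 (2.48) and Itln1 (2.18), besides Lyz1 and Ang4.

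Sums of enterocyte genes stood above even but within the 1.5-fold limit. Lipid absorption genes had 4 of 12 higher and 0 lower with a summed ratio of 1.36, among them the fatty acid transporter Cd36 (1.67 times), the apolipoprotein Apoa4 (1.53) and the cholesterol transporter Npc1l1 (1.51). The enterocyte markers had 2 of 10 higher with a summed ratio of 1.34, including the lactase gene Lct at 1.66 times. All 7 counted tuft markers were lower (summed ratio 0.351), as were 7 of 10 enteroendocrine markers (0.687), with Gip at 0.548 times and Cck at 0.593 times. Of the 8 stem markers 5 were lower (0.544), including Olfm4 at 0.508 and Smoc2 at 0.597 times, and of 16 genes of the Wnt and Notch stem niche 4 were lower and 0 higher (0.747). Goblet markers (1.1) and cycling markers (1.03) had no member past the limit, though their medians lay at percentiles 98.96 and 99.99 of the matched random lists. Among the 12 lowest genes, Lrmp, Alox5ap, Kctd12, Sfrp5, Fyb and Tuba1a lay between 0.270 and 0.466 times. The lowest of all, the neurotensin gene Nts at 0.0345 times, rested on 1 cell, since 3115 of its 3144 singlet UMIs came from a single barcode. The ghrelin gene Ghrl, at 0.222 times, had 59.4% of its singlet UMIs in 1 barcode.

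Summed ratios of lists of cell stress and structure stayed within 1.5-fold in the small intestine. The summed ratio was 0.900 for the dissociation response, 0.882 for heat shock, 0.968 for epithelial adhesion and 1.12 for mitochondrially encoded genes. None of these lists had a member past 1.5-fold. Their medians lay at percentiles 30.9, 0.62, 93.2 and 100 of the random lists matched on expression. The heat shock and mitochondrial shifts were thus small but at the ends of that range. MHC class II genes stood at 0.896, interferon genes at 1.05 with 1 of 6 higher, crypt to villus zone genes at 1.30 with 1 of 5 higher, and matrix genes at 0.860 with 3 counted. Endothelial junction genes stood at 0.992 with 1 of 3 lower, and endothelial markers at 0.767 with 2 counted. Genes of immune cells were scarce. Lyz2, the only counted gene of the myeloid list, stood at 4.12 times, and whether its UMIs came from immune cells was not tested. The B cell gene Cd79a stood at 4.31 times (2.39 to 8.33). No T cell, fibroblast, erythroid or haemoglobin marker was in both tables. By the size rule 166 of 11674 counted genes were higher and 452 lower, and by TMM scaling, which moved the median of all genes from -0.10 to 0.003 on the log2 scale, 260 were higher and 333 lower.

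**Figure D1:**
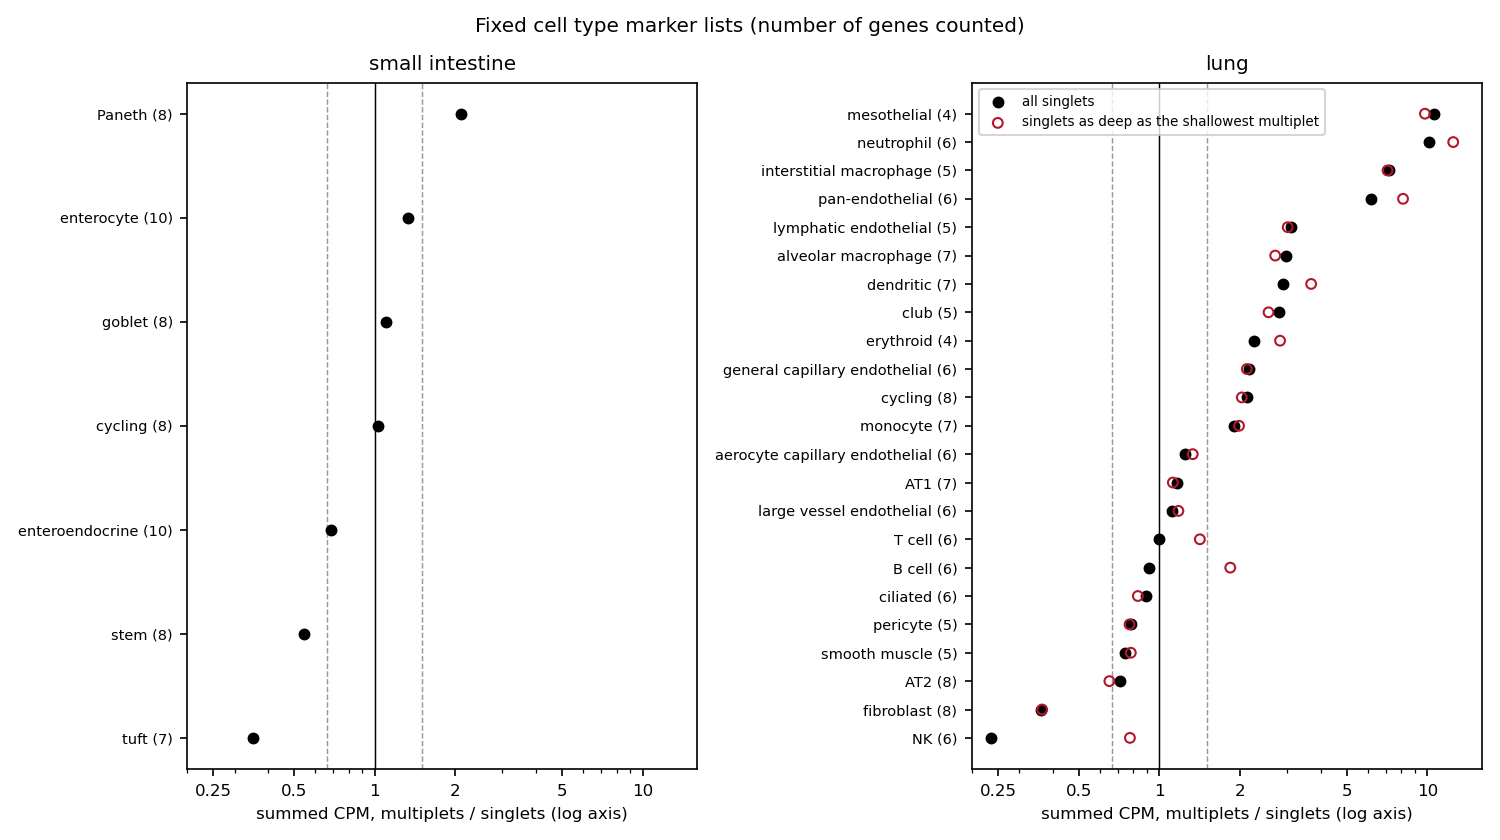
Summed CPM of each fixed marker list in multiplets over singlets, on a log axis, for small intestine and lung, with dashed lines at 1.5-fold in either direction. Black points use all singlets and red open circles, in the lung, use singlets at least as deep as the shallowest multiplet; Paneth markers stood at 2.10 and tuft markers at 0.351 in the small intestine, and mesothelial markers at 10.6 and fibroblast markers at 0.361 in the lung.

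The same comparison in the lung gave larger differences. RNA of endothelial cells, macrophages, neutrophils and mesothelial cells was higher in multiplets and RNA of fibroblasts was lower. The endothelin receptor gene Ednrb, found in capillary aerocytes, was 12.5 times higher (10.7 to 14.9), Msln, a marker of the mesothelium that lines the lung, 12.7 times (11.2 to 14.4), the complement gene C1qa 12.5 times (11.6 to 13.5) and the neutrophil gene S100a9 10.6 times (10.3 to 10.9). The matrix gene Lum stood at 0.104 times its singlet level (0.0931 to 0.115) and Scara5, a fibroblast gene, at 0.115 times.

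Endothelial markers shared by all vessels were higher in 6 of 6, with a summed ratio of 6.14, among them the cadherin gene Cdh5 (6.99 times), the claudin gene Cldn5 (6.57) and Pecam1 (5.04). General capillary markers were higher in 6 of 6 (2.17), lymphatic markers in 5 of 5 (3.10), aerocyte markers in 4 of 6 with 1 lower (1.24) and large vessel markers in 3 of 6 with 1 lower (1.11). Endothelial junction genes were higher in 5 of 7 (2.94). Car4, a carbonic anhydrase gene of capillaries, stood at 5.33 times. Mesothelial markers were higher in 4 of 4 (10.6).

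Myeloid genes were higher across lists. Interstitial macrophage markers were higher in 5 of 5 (summed ratio 7.18), with C1qc at 12.3 times and C1qb at 10.8 times, and the chemokine genes Cxcl13 and Pf4 stood at 12.5 and 12.3 times. Neutrophil markers were higher in 6 of 6 (10.1), with S100a8 at 10.1 times and Mmp9 at 10.3 times (15.4 against singlets as deep as multiplets), and inflammatory genes of neutrophils and monocytes in 8 of 9 (4.46). Alveolar macrophage markers were higher in 7 of 7 (2.96), dendritic markers in 6 of 7 (2.89), monocyte markers in 5 of 7 with 1 lower (1.89) and MHC class II genes in 7 of 7 (2.34). Cycling markers were higher in 7 of 8 (2.12), with Mki67 at 6.63 times and Ube2c at 10.2 times. Ltf, the lactoferrin gene, had the highest ratio at 17.7 times (15.7 to 20.1), but 84.1% of its multiplet UMIs lay in 10 barcodes, and with each barcode weighted equally its ratio was 5.90.

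All 8 fibroblast markers were lower (0.361), among them the collagen gene Col1a1 (0.387 times) and Dcn (0.265), and 11 of 13 basement membrane and matrix genes were lower (0.470), including the elastin gene Eln at 0.469 times. Also among the 12 lowest were Pi16, Ccl11, Colq, Serpinf1, Aspn, Bmper, Fgfr4 and Slc7a10, between 0.15 and 0.246 times. The granzyme genes Gzma (0.223) and Gzmb (0.253) and all 6 NK markers (0.236) were lower too, but these depended on depth: NK singlets had a median of 3459 UMIs and no lung multiplet had fewer than 5006. Against the 4770 singlets at least that deep, a comparison chosen after seeing the data, Gzma stood at 0.714, Gzmb at 0.655 and the NK list at 0.776, whereas with all singlets and each barcode weighted equally Gzma stood at 0.0963 and Gzmb at 0.124. Against the deeper singlets B cell markers moved from 0.912 to 1.84 and T cell markers from 0.994 to 1.42.

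Epithelial genes differed by type in the lung. Surfactant genes (0.715, 0 of 10 past the limit) and type II pneumocyte markers (0.714, 0 of 8) stood below even in the sums but within the limit. The surfactant protein gene Sftpc stood at 0.712 times, but with each barcode weighted equally the surfactant list turned to 1.13. Club cell markers were higher in 4 of 5 (2.78) and type I pneumocyte markers in 4 of 7 (1.16), whereas 0 of 6 ciliated markers passed the limit (0.890). Of the angiogenic signals of the alveolus 7 of 11 were higher and 2 lower (0.817), of smooth muscle markers 2 of 5 were higher and 2 lower (0.744), and of pericyte markers 3 of 5 were higher and 2 lower (0.780). Erythroid (2.26) and haemoglobin genes (2.27) were each higher in 3 of 4, platelet markers in 1 of 2 and the 1 counted mast or basophil gene stood at 2.91. The sums of the dissociation response (0.892), heat shock (0.968, 1 of 10 lower), epithelial adhesion (1.05, 4 of 17 higher) and mitochondrially encoded genes (0.952) stood near even. Interferon genes had a summed ratio of 1.15, but 4 of 10 were higher and 2 lower, with a median log2 ratio of 0.478. By the size rule 2402 of 15098 genes were higher and 2077 lower. None of the 8 lists compared between the tissues stood above even in one tissue and below it in the other by the margin fixed beforehand.

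Some of these genes lie as follows on GRCm38. Defa22 spans 21162277 to 21163249 and Defa24 spans 21734494 to 21735471 on chromosome 8. Lyz1 spans 117287797 to 117292868, Lgr5 spans 115450311 to 115587780 and Lum spans 97565128 to 97572703 on chromosome 10. Ednrb spans 103814625 to 103844402 on chromosome 14, Msln spans 25748613 to 25754378 on chromosome 17 and C1qa spans 136895917 to 136898803 on chromosome 4.

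Co-detection of marker lists asks, without any class profile, whether RNA of a pair of cell types shared a barcode more often in multiplets. At 1000 UMIs per barcode, Paneth and stem markers came together in 492 of 3671 intestinal multiplets, or 13.4% (12.3 to 14.5), against 411 of 5279 singlets, or 7.79% (7.08 to 8.54). Goblet and stem markers came together in 11.9% against 6.12%, and Paneth and goblet markers in 23.8% against 12.9%. In the lung, endothelial and type I pneumocyte markers came together in 257 of 4729 multiplets, or 5.43% (4.81 to 6.12), against 24 of 6084 singlets, or 0.394% (0.253 to 0.586). T cell and interstitial macrophage markers did so in 0.529% against 0.0329%, and alveolar macrophage and type II pneumocyte markers in 3.93% against 1.36%. These shares were not adjusted for the abundance of each RNA, so a more abundant RNA alone can raise them. Summed Paneth markers stood at 2.10 times in intestinal multiplets. In the lung, summed endothelial markers stood at 6.14 times and interstitial macrophage markers at 7.18 times.

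Intestinal co-detection was also frequent in single cells. Paneth markers reached 2 UMIs in 21.2% of intestinal singlets although 1.67% were Paneth cells, and type II pneumocyte markers did so in 53.6% of lung singlets although 16.6% were of that class, so co-detection in singlets is the background for these values. The share of lung barcodes with markers of 2 or more types was 58.1% in multiplets and 57.9% in singlets. Hopx, in the type I pneumocyte list, was also found in barcodes called endothelial alone at 810 CPM, so that list is not specific to type I pneumocytes. Without thinning, Paneth with stem markers reached 68.3% and 59.1% and endothelial with type I pneumocyte markers 17.7% and 2.51%.

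Fitting each barcode as a mixture of the singlet classes asks how many cell types a multiplet held. In the small intestine 57.1% of multiplets (55.5 to 58.7; 2096 of 3671) were given at least 2 classes, against 43.5% of held-out singlets (42.1 to 44.8; 2294 of 5279). In the lung 24.1% of multiplets were (22.9 to 25.4; 1141 of 4729), against 11.3% of singlets (10.5 to 12.1; 689 of 6084). Exactly 2 classes were called in 46.3% of intestinal and 21% of lung multiplets, and exactly 3 in 10.5% and 2.96%. With classes that grade into each other merged, a choice made after seeing the data, the shares were 31.2% against 15.9% in the small intestine and 19.8% against 4.80% in the lung. In the lung a weight limit of 0.25 gave 14.8% of multiplets. Clusters of cells of the same class count as 1 class here.

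Paneth cells were called in 274 intestinal multiplets, 7.46% of all, and goblet cells in 29.9%, whereas tuft cells were called in 46. In the lung alveolar macrophages were called in 19.8% of multiplets against a share of 3.73% among singlets, macrophages in 22.5% against 4.65% and endothelial cells in 12.3% against 1.96%. At 5000 UMIs per barcode the neutrophil gene S100a8 had a UMI in 51.1% of multiplets called macrophage alone. In the 235 macrophage singlets at least that deep it was 14.5%, and no neutrophil class was among the singlets. A multiplet may hold several cells, which alone can raise the share with a UMI. Of the 580 lung multiplets with an endothelial call 354 had no other class.

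The pair comparison asks which cell types occurred together more often than their totals among mixed barcodes would give. Paneth with stem cells, neighbours in the crypt base, were called together in 69 multiplets where 13.6 were expected, a ratio of 5.08 (3.95 to 6.43), and in 0 of 5279 held-out singlets, which allows a share of up to 0.0568% by the limit of 3 counts (exact interval up to 0.0699%). Only 88 of these singlets were Paneth and 587 stem cells, so the limit over all singlets is tighter than those cells alone would give. Of synthetic Paneth with stem doublets 46% were recovered. Paneth with transit amplifying cells stood at 1.08 (0.771 to 1.47). With non-negative least squares Paneth cells stood at 2.93 with stem cells and 2.91 with transit amplifying cells, so the contrast between them was absent there. Merging stem, transit amplifying and early progenitor cells into 1 class gave 1.14 with Paneth cells (0.946 to 1.37). Paneth with early progenitors stood at 0.286, while Paneth with late-1 progenitors had 0 observed against 15.4 expected (0 to 0.24), with 22% of synthetic doublets recovered. Goblet with stem cells had 58 observed against 98.2 expected, a ratio of 0.590 (0.448 to 0.763), or 0.303 among barcodes with exactly 2 classes.

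Enterocytes with late-1 progenitors had a ratio of 5.76 (4.91 to 6.72), enterocytes with late-2 progenitors 3.91 (2.95 to 5.09) and the late progenitors with each other 3.85 (3.28 to 4.50), but these pairs were also called in 132, 28 and 123 held-out singlets. With non-negative least squares they stood at 2.59, 1.30 and 2.34. Stem with transit amplifying cells stood at 1.5 (1.33 to 1.70) and were called together in 470 singlets, and the ratio was 5.50 with non-negative least squares. Goblet with transit amplifying cells stood at 1.52 (1.38 to 1.68) and transit amplifying with tuft cells at 1.68 (1.02 to 2.59), and both turned with non-negative least squares, to 0.519 and 0.849. Enteroendocrine with stem cells stood at 1.56 (0.778 to 2.79), and from 0.431 to 1.97 over 9 alternatives. The other 3 of the 4 lowest pairs, beside Paneth with late-1 progenitors, joined the absorptive lineage with stem or transit amplifying cells: late-2 progenitors with stem cells had 0 observed against 36.2 expected (0 to 0.102), late-1 progenitors with stem cells a ratio of 0.0695 (24% of synthetic doublets recovered) and enterocytes with transit amplifying cells 0.0742. With late progenitors and enterocytes merged, and stem, transit amplifying and early progenitor cells merged, those classes stood at 0.952 (0.852 to 1.06). That merged pair takes in early with late-1 (242 observed) and late-2 progenitors (77 observed), also called in 437 and 110 held-out singlets. It therefore cannot decide on stem or transit amplifying cells alone. Over 9 alternatives that keep the classes, late-2 progenitors with stem cells reached at most 0.0556 and late-1 progenitors with stem cells 0.103. Enterocytes with transit amplifying cells reached at most 0.113. No T cell class was among the intestinal singlets, so enterocytes with T cells could not be scored.

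In the lung, endothelial cells were called together with alveolar epithelial classes more often than expected. Endothelial cells with type II pneumocytes had 41 observed against 10.6 expected, a ratio of 3.89 (2.79 to 5.27), with 4 held-out singlets so called and 86% of synthetic doublets recovered, and 2.57 with non-negative least squares. With type I pneumocytes they had 23 observed against 7.09 expected, a ratio of 3.25 (2.06 to 4.87), with 0 of 6084 held-out singlets (up to 0.0493% by the limit of 3 counts, exact interval up to 0.0606%) and a reference of 6 cells. Only 119 of these singlets were endothelial cells and 6 type I pneumocytes, so the limit over all singlets is tighter than those cells alone would give. The ratio with type I pneumocytes was 6.45 among barcodes with exactly 2 classes and 5.91 with non-negative least squares. It ran from 2.42 to 295 over 10 alternatives. Endothelial cells stood at 1.02 with fibroblast-1 and 0.706 with fibroblast-2 cells. With the fibroblast classes merged they stood at 2.13 (1.57 to 2.82) with fibroblasts and 2.03 (1.14 to 3.35) with mesothelial cells. Pairing with type I pneumocytes was not particular to endothelial cells. With merged classes type I pneumocytes had 26 observed against 9.67 expected with endothelial cells and 28 against 4.16 with club cells. They had 9 against 2.15 with ciliated and 9 against 2.71 with mesothelial cells, but 8 against 8.28 with fibroblasts. Type I with type II pneumocytes had 3 observed and 3.26 expected, too few to report a ratio.

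Among immune cells in the lung some pairs stood above expectation and others did not. B cells with macrophages stood at 2.14 (1.73 to 2.62; 94 observed), alveolar macrophages with macrophages at 1.86 (1.60 to 2.15), macrophages with T cells at 1.83 (1.55 to 2.15; 150 observed) and NK with T cells at 2.76 (1.71 to 4.22), or 4.67 with non-negative least squares. The intervals included 1 for macrophages with NK cells (1.38), alveolar macrophages with NK cells (1.22, or 2.94 with non-negative least squares) and alveolar macrophages with B cells (0.805, or 2.14). B with T cells stood at 1.5 (1.03 to 2.11) but at 0.656 among barcodes with exactly 2 classes. NK with T cells were also called in 24 held-out singlets, against 17, 8 and 20 for the other three. Alveolar macrophages with T cells stood at 1.58 (1.248 to 1.98) but at 0.700 with non-negative least squares. With the expectation from singlet class shares, macrophages stood at 14.5 with T cells, 16.01 with B cells and 25.8 with alveolar macrophages. Both fibroblast classes together had a ratio of 4.58 (4.0 to 5.22), with 398 held-out singlets so called, and 1.29 with the expectation from singlet shares. Fibroblast-2 cells were seldom paired with immune cells, at 0.104 with B cells, 0.111 with T cells, 0.15 with NK cells and 0.153 with macrophages. The fibroblast pair calls fill much of the fibroblast-2 total, and with the fibroblast classes merged these values were 0.553 (0.253 to 1.05), 0.489, 0.542 (0.112 to 1.58) and 0.693. Alveolar macrophages with type II pneumocytes stood at 0.836 (0.457 to 1.40), but at 2.11 with non-negative least squares.

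**Figure D2:**
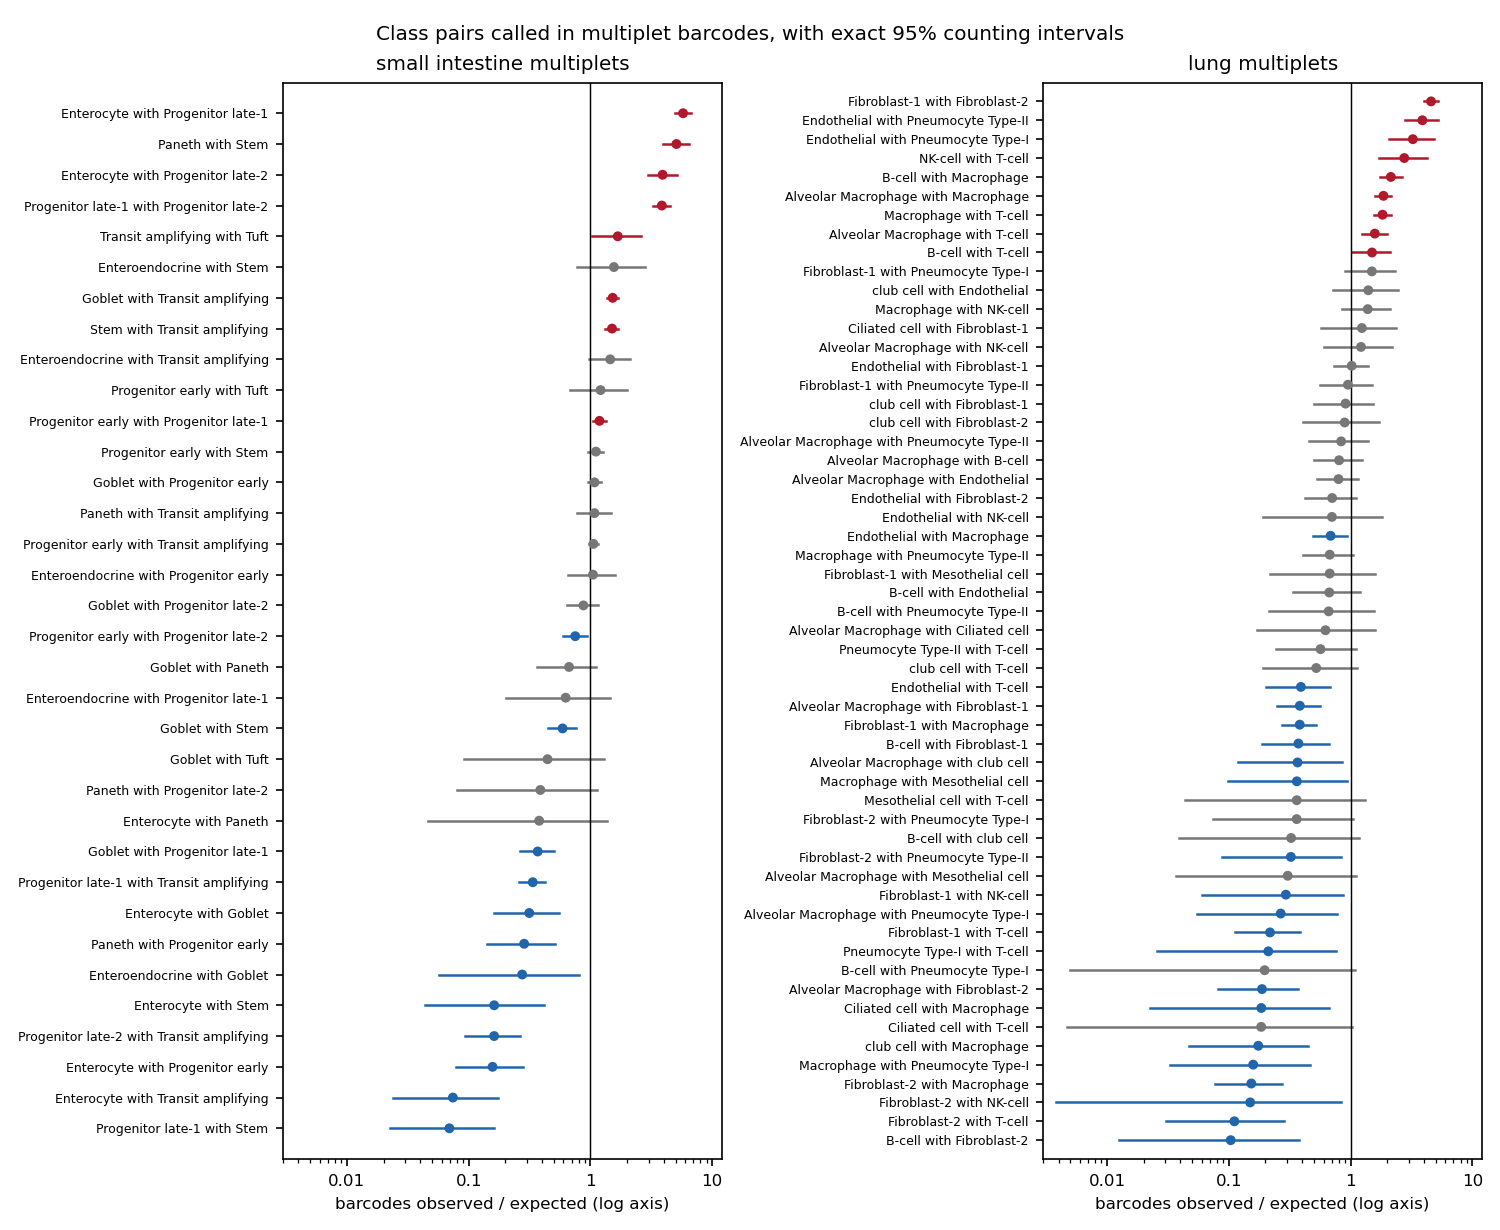
Pairs of classes called together in multiplets, as observed over expected count on a log axis, for small intestine and lung; bars are exact 95% intervals of the observed count, red where the interval lies above 1, blue below 1 and grey where it includes 1. Pairs with 0 observed are left out; Paneth with stem cells stood at 5.08 and endothelial cells with type II pneumocytes at 3.89.

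Genes outside the mixture had more or less RNA in multiplets than the fitted weights of all classes predicted. In the small intestine 43 of 9742 genes were over 1.5 times the prediction and 61 under it by as much. The highest were Plb1, a brush border phospholipase gene (5.13 times), Fgf15, a hormone gene of the ileum (3.95), Fam151a (3.81), the defensin genes Defa22, Defa21, Defa20 and Defa35 (between 2.11 and 2.88), Slc34a2 (2.53), Cubn (2.22) and Sval1 (2.17). The lowest were Sfrp5 (0.438), Slc1a2 (0.493), Afap1l1 (0.502), Cfi (0.504) and Nts (0.0825), the last resting on the single cell named above.

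In the lung 294 of 12571 genes were over the prediction by 1.5 times and 167 under it. Among the highest were genes of tissue-resident macrophages, the lectin gene Cd209f (34.9 times), the folate receptor gene Folr2 (23.0), Cxcl13 (23.6), Ccl8 (17.0) and Ccl12 (10.3), and of muscle, Actc1 (47.6) and the smooth muscle myosin gene Myh11 (13.9). Cd209f stood at 17.6 with profiles that weighted each singlet equally. The predictions rest on few singlet UMIs, with 4 for Cd209f, 11 each for Folr2, Ccl12 and Actc1, 10 for Camp, 5 for Krt13 and 8 for Krt4. Several rested on few barcodes: 91.6% of Camp UMIs (41.6 times), 87.1% of Krt13 UMIs (12.3 times) and 65.2% of Krt4 UMIs (10.2 times) lay in 1 multiplet barcode, and 90.4% of Actc1 UMIs lay in 10. The lowest were Myoc (0.0155), with 92.5% of its singlet UMIs in 10 barcodes, Upk3a (0.219), the fibroblast genes Lum (0.272) and Scara5 (0.282), and Pi16 (0.325).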

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

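The alternatives with merged classes, with barcodes thinned to 5000 UMIs before the fit and with singlets as deep as the shallowest multiplet were chosen after seeing the data. Where a value moved below, the cause was not tested unless stated. Limits of the data come first: with 1 library per group an animal, a dissociation and a library are the same unit, intervals cover counting error, and the type I pneumocyte and mesothelial references rest on 6 and 10 cells. Requiring 1000 UMIs removed no barcode, and the depth floor removed no intestinal singlet, so these say nothing about stability. The counts that follow leave these out. Of the values for lists 98 stayed within 1.1 times and 10 moved, and of those for genes against the mixture 48 stayed within 1.1 times and 12 moved. TMM, DESeq2 size factors and CPM without mitochondrial, ribosomal protein and haemoglobin genes each multiply every summed ratio of a tissue by 1 factor. That factor was always within 1.1 times, so under these scalings no list could move. Most of the 98 values came from them and say nothing about stability. Of those for named genes in the sums 139 stayed within their counting interval and 77 moved. No gene crossed 1, and no list past 1.5-fold did, but the lung surfactant list, at 0.715, turned to 1.13 with barcodes weighted equally. The named genes were chosen for the most extreme ratios, so scaling by such a factor could not carry them across 1. Of the pair values 702 stayed within the interval, 149 moved and 15 reversed, which counts only pairs whose interval excluded 1. Paneth with stem cells stayed above 1 throughout, from 2.93 to 5.62 over 9 alternatives that keep the stem class (with stem, transit amplifying and early progenitor cells merged, Paneth cells with that class stood at 1.14, 0.946 to 1.37), as did endothelial cells with type II pneumocytes, from 2.57 to 3.97 over 10, and macrophages with T cells, from 1.48 to 14.5 over 10.

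The number of intestinal genes over 1.5-fold higher, 166, was 260 with TMM, 256 with DESeq2 size factors, 309 with the mean of barcode CPM, 613 with no minimum and 90 with a minimum of 200 UMIs. The number lower, 452, was 1329 with no minimum and 164 with a minimum of 200, where more or fewer genes were counted. In the lung the number lower, 2077, was 3329 with no minimum.

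Paneth with stem co-detection in singlets and multiplets was 2.75% and 7.33% at 500 UMIs, 16.6% and 24.1% at 2000, 59.1% and 68.3% without thinning, and 3.24% and 8.36% at 3 UMIs per list. Endothelial with type I pneumocyte co-detection was 0.197% and 3.28% at 500 UMIs, 0.822% and 7.78% at 2000, 2.51% and 17.7% without thinning, and 4.14% in multiplets at 3 UMIs per list.

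Intestinal multiplets with 2 or more classes, 57.1%, were 65.2% at a weight of 0.10, 38.8% at 0.25, 69.98% with non-negative least squares, 53.0% with 20 genes per class, 58.8% with 80 and 31.2% with merged classes. In the lung, 24.1% became 28.2% at 0.10, 14.8% at 0.25, 22.1% with 20 genes and 19.8% with merged classes.

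With non-negative least squares, Paneth with stem cells stood at 2.93, endothelial cells with type II pneumocytes at 2.57 and macrophages with T cells at 2.75. It raised Paneth with transit amplifying cells from 1.08 to 2.91 and alveolar macrophages with type II pneumocytes from 0.836 to 2.11. It turned enteroendocrine with goblet cells to 1.62, goblet with transit amplifying cells to 0.519, transit amplifying with tuft cells to 0.849 and alveolar macrophages with T cells to 0.700. Macrophages with T cells stood at 1.54 with 20 genes per class and at 1.48 with merged classes. With the expectation from singlet class shares they stood at 14.5. That expectation turned early with late-2 progenitors to 1.32, transit amplifying with tuft cells to 0.686, and alveolar macrophages with club cells to 3.31 and with type I pneumocytes to 20.2. It also turned macrophages with club cells to 2.12, with endothelial cells to 11.4, with mesothelial cells to 12.9 and with type I pneumocytes to 16.2, and T cells with endothelial cells to 2.76 and with type I pneumocytes to 9.14. Classes rarer among singlets than multiplets get a small expectation there by construction. Among barcodes with exactly 2 classes, B with T cells turned to 0.656.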

Other observations

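The tests of more Paneth RNA, of reads shared between defensins, of free Paneth RNA, of barcodes with 2 or more classes and of the fibroblast share were chosen only after the results they weigh were seen, and so were the genes and the equal depth used for partners. Lung barcodes with at least 5000 UMIs were thinned to that depth and shallower ones were left out. This kept 235 of 283 macrophage, 62 of 119 endothelial and 32 of 190 B cell singlets. In C1qa and S100a8, macrophage multiplets with B or T cells differed from those without another class. In a barcode of 2 classes part of the 5000 UMIs comes from the partner, which alone lowers the share for genes the partner lacks. The lower S100a8 shares with a partner may rest on this, whereas C1qa went the other way. Between B and T cells as partner the intervals overlapped. C1qa, a complement gene of interstitial macrophages, had a UMI in 42.6% of 61 multiplets of B cells with macrophages (30.0 to 55.9) and in 33.0% of 97 of macrophages with T cells (23.8 to 43.3). The share was 18.7% of 577 macrophage multiplets without another class (15.6 to 22.1) and 8.09% of 235 macrophage singlets. A multiplet may hold several macrophages, which alone can raise the share with a UMI, so shares of multiplets and singlets compare unlike units. The mean C1qa level was 715 CPM in these multiplets and 210 CPM in these singlets. As background the C1qa share was 2 of 19 B cell multiplets, 1 of 71 T cell multiplets and 1.08% of 830 type II pneumocyte multiplets, each without another class. Cd209a, a dendritic cell gene, had a UMI in 32.0% of macrophage with T cell multiplets (22.9 to 42.2), against 17.3% of macrophage multiplets without another class (14.3 to 20.7), 16.6% of macrophage singlets and 0 of 71 T cell multiplets. With B cells it was 21.3% (11.9 to 33.7), an interval that overlaps the one with T cells. S100a8, a neutrophil gene, had a UMI in 51.1% of macrophage multiplets without another class (47.0 to 55.3), against 22.7% with T cells and 21.3% with B cells. Its background was 5.78% of type II pneumocyte, 7.75% of fibroblast-1, 9.04% of endothelial and 9.86% of T cell multiplets, each without another class. Among 22 multiplets of endothelial cells with type I pneumocytes it reached 27.3% (10.7 to 50.2). No neutrophil class was among the singlet classes, so barcodes with neutrophil RNA had no class of their own.

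At the same depth the capillary gene Car4 had a UMI in 55.1% of 354 endothelial multiplets without another class (49.7 to 60.3). It had one in 20.97% of 62 endothelial singlets (11.7 to 33.2) and in 0.964% of type II pneumocyte multiplets as background. An endothelial multiplet may hold several endothelial cells, which alone can raise the share with a UMI. The mean level, which cell number alone should not raise, was 1043.5 CPM in the endothelial multiplets and 274.2 CPM in the endothelial singlets. Car4 was seen in 36.4% of 22 multiplets of endothelial cells with type I pneumocytes (17.2 to 59.3). With type II pneumocytes it was seen in 28.9% of 38 (15.4 to 45.9). In these mixed barcodes part of the UMIs comes from the pneumocytes, which alone can lower the Car4 share. Ccl21a, a lymphatic endothelial chemokine gene, went the other way, with a UMI in 11.6% of endothelial multiplets without another class (8.44 to 15.4) and in 32.3% of endothelial singlets (20.9 to 45.3), against 0.964% of type II pneumocyte multiplets and 0.396% of type II pneumocyte singlets as background. With type I pneumocytes it was seen in 0 of 22, which is too few to tell from the share in endothelial multiplets without another class. No test was made between libraries.

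Paneth genes were unequally higher in intestinal multiplets, and more Paneth RNA of the same kind could not give this alone, since among the 8 Paneth markers fixed beforehand the ratio of Paneth barcodes without another class to Paneth singlets ran from 0.614 for Defa30 to 3.19 for Defa22, 5.19 times apart. Reads shared between near-identical defensins stay open for the defensins: of 5 other Paneth genes Ang4 stood at 2.05 times, while Lyz1 (1.18), Mmp7 (1.07), Itln1 (1.1) and Mptx2 (1.46) lay within 1.5-fold, with a median of 1.18. A candidate explanation is a different share of Defa22-high Paneth cells: Defa22 made up at least 10% of Defa22 plus Defa24 in 72.6% of 157 multiplet barcodes (64.9 to 79.4) but in 21.6% of 88 singlets (13.5 to 31.6), and the median above that limit was 23.6% in multiplets and 25.2% in singlets. A multiplet barcode called Paneth alone may hold several Paneth cells, and 1 that mixes high and low cells can pass the limit. The 72.6% and 21.6% therefore compare unlike units and do not measure the share of Defa22-high cells. The candidate may also be only part of the cause. Below the limit the median was 1.08% in multiplets and 0.0944% in singlets, and 41 of the 157 multiplet barcodes lay between 5 and 20%. Whether the libraries came from different animals or stretches of gut is not in the labels, and both stay open and untested.

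Paneth with stem cells were paired above expectation in multiplets. Random pairing among stem, transit amplifying, early progenitor, Paneth, goblet, tuft and enteroendocrine classes could not give this with the Poisson mixture. With these classes only, the ratio was 3.89 (3.03 to 4.92, with 17.7 expected). That set is wider than the crypt base, so it cannot exclude random pairing among crypt base cells. With stem, transit amplifying and early progenitor cells merged, Paneth cells with that class stood at 1.14 (0.946 to 1.37). Free Paneth RNA spread over all barcodes is argued against by Paneth markers at 9755 CPM in stem multiplets without another class, 7.44 times the 1311 CPM of early progenitor multiplets without another class. With non-negative least squares the pair stood at 2.93 and Paneth with transit amplifying cells at 2.91, so preference for stem cells over these rests on the mixture used. Physical contact in the crypt, which the multiplet design addresses, may be the reason, a hypothesis found and tested on the same data, and so may contact made after dissociation, for which these libraries hold no control.

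Endothelial, mesothelial, C1q and neutrophil markers were higher in lung multiplets. Barcodes of 2 or more classes could not be the whole source for endothelial and mesothelial markers, since in multiplets of 1 class the lower of these ratios was 6.55. Neutrophils have no class of their own. Interstitial macrophages have none apart from the macrophage class, where C1qa had a UMI in 8.09% of singlets at 5000 UMIs. For these 2 types the lower ratio in multiplets of 1 class, 5.09, leaves it open. A lower fibroblast share alone would raise other types alike, but against singlets as deep as multiplets the lowest of the 4 ratios was 3.86 times the highest among NK (0.776), type II pneumocyte (0.651), T cell (1.42) and B cell (1.84) markers. The depth floor of the multiplet library could not be the source, since against those singlets the lowest of the 4 ratios was 7.10. That comparison does not test limits on the singlets themselves. Lung singlets with counts had at least 2175 UMIs and 1137 genes, so shallower single cells could not be examined. Incomplete dissociation of these cell types, with clusters of 1 type, is a possible explanation that was not tested, and a difference between animals or between preparations of the libraries stays open too.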
